A study of Homo sapiens with 2 samples.

How the data were processed

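The data were 2 one-colour Agilent human whole-genome expression arrays of LNCaP, an established androgen-sensitive prostate cancer cell line. One array held RNA of cells transduced with a lentiviral non-targeting shRNA (control), the other RNA of cells transduced with an shRNA against GABARAPL1 (knockdown). Group membership was taken from the genotype labels. There was 1 array per group and the arrays came from different slides, so slide, array and knockdown cannot be told apart, and no difference between the groups could be tested against replicate spread; the intervals given cover counting or the spread over genes within these 2 arrays only. The labels name the Cy5 dye, whereas the scanner files hold a single channel, the green one; that channel was used.

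Per the file headers, the arrays were read with Feature Extraction 10.7.3.1, and the deposited intensity values are processed signals on a linear scale, background-subtracted and detrended within the array, with signals not above background replaced by a small surrogate value. The raw mean spot intensity and local background in the same deposited files were used for 1 alternative. Probe coordinates in those files are on hg19. The authors' value table holds values whose scale and processing were not given in the sources used here. Set against the scanner values, each of its columns followed its own array with a correlation of 1.00 across probes and a slope of 0.993 (control) and 0.985 (knockdown) against log2 signal, and the sorted columns differed by at most 0.02. The deposited table was therefore read as log2 values brought to one distribution, not centred per gene, with knockdown and control in the direction of the labels. Both columns had a median of 6.69, and the exact normalization stays unknown. It served as an alternative.

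Each array had 43376 non-control spots for 41000 probes, of which 264 were printed 10 times. Spots flagged as non-uniform or population outliers were left out, spots of a probe were averaged, and log2 processed signals were scaled by subtracting each array's 75th percentile. A probe counted as measured when it was well above background and not saturated on both arrays; no spot was saturated. A gene's value was the mean over its measured probes. Probes were named through their RefSeq accession in a gene table of assembly GRCh38.p14, used for names only: 27294 of 41000 probes matched, the other 13706 kept the name in the files, and 29565 probes carried a current symbol, for 18612 genes. Gene counts use genes with a current symbol. Genes well above background on 1 array only were given a lower bound on the fold, the bright array's value over the higher of the dim array's own signal and the lowest signal well above background there. Technical spread came from the replicated probes. It covers the printing and reading of spots within an array, and not labelling, culture or transduction; the number of arrays limits the precision.

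Before the data were examined, the differences, counts and size threshold of 2-fold, the alternatives and 25 gene lists were fixed. The lists cover the ATG8 family, core autophagy, lysosome, androgen-induced and androgen-repressed genes, luminal identity, G1/S and replication, G2/M and mitosis, p53 targets, interferon, ER chaperone and stress genes, ATF4 targets, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, mesenchymal, basal epithelial, neuroendocrine and other-cell-type markers, immediate early, NF-κB and inflammation, FOXO-induced, heat shock, and NRF2 and oxidative stress genes. A list's median difference was placed among 10000 random lists of the same size drawn with replacement from genes in the same of 20 bins of mean level. A list was said to stand apart below the 2.5th or above the 97.5th percentile if at least 5 members were measured; of 25 lists, 1.25 would lie outside by chance. Genes of a list are co-regulated, so a percentile describes these 2 arrays only.

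Genes were named by a rule fixed at the same time. It took the ATG8 family; the 10 genes with the largest difference in each direction among those at or above the median level whose probes all differed the same way; the 3 largest bounds in each direction among genes measured on 1 array; up to 4 members of each list with the largest absolute difference; and KLK3, TMPRSS2 and FKBP5. Some genes that the rule takes are not reported here. Other named genes are marked as chosen after their values were seen.

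The alternatives were centring on the median, quantile normalization, cyclic loess, normexp background correction (offset 50) with quantile normalization, the deposited value table, no filter on dim probes, probes in the upper part of the level range, the brightest probe per gene, 10 level bins, and a 1.5-fold threshold. Added after the data were examined were subtraction of the local median of 11 by 11 spots, removal of a group of low spots, removal of a trend on probe GC content and level, restriction to genes with 2 or more probes, the filter and brightest-probe alternatives gene by gene, and, for 1 test of marker genes, leaving out markers already seen. The steps were tested on simulated arrays of 14088 genes with known differences. Noise was drawn independently per probe, with about the spread of the real differences (SD 0.39 below and 0.27 above the median level). Of genes set at 1.5, 98% passed 2-fold, and of those at -1.5 (log2) 94%. All genes set at 2.5 or -2.5 did, and 42 unchanged genes did too. Of 200 unchanged lists 13 lay outside the percentile limits, and 100 of 100 lists of 30 genes shifted by -0.25 were found. Real probes of a gene were correlated (r of 0.58) and list members are co-regulated, so these counts give no false-call rate for the real arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.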

Results

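Gene expression was measured in LNCaP cells carrying an shRNA against GABARAPL1, which encodes an ATG8-family protein of the autophagosome membrane, and in LNCaP cells carrying a non-targeting shRNA. Each group had 1 array, so the differences below have no replicate check. Of 43376 non-control spots, 70.5% were well above background on the control array and 74.9% on the knockdown array, the 75th percentile of processed signal was 913 and 908, and the median coefficient of variation of replicated spots was 4.29% and 4.08%. In all, 14088 genes were measured on both arrays, and their levels correlated with a Pearson r of 0.992 across genes, which are not independent replicates.

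The targeted transcript was examined first. GABARAPL1 was about 5-fold lower on the knockdown array, with a log2 difference of -2.34. Its 2 probes, on chromosome 12 at 10375058 to 10375117 and at 10374676 to 10374735 (hg19), read 2042 and 619 on the control array against 384 and 124 on the knockdown array. These are 5.23-fold and 4.93-fold differences, or reductions of 80.9% and 79.7% after scaling; the labels give a reduction of at least 75% by quantitative PCR. The technical spread (SD) of a difference was 0.09 over replicated probes at or above the median level and 0.18 over those below it. GABARAPL1 lay just above that median by its mean level, and below it on the knockdown array. The probe for GABARAPL3, a pseudogene that is a near copy of GABARAPL1, was lower by a similar amount, at -2.25, and the array cannot tell whether it reads its own transcript or that of GABARAPL1; with normexp background correction its difference was -1.17.

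The other ATG8-family transcripts lay close to 0. GABARAP differed by 0.09, GABARAPL2 by -0.08, MAP1LC3B by 0.01 (its sign turned under 4 of the 5 other scalings and backgrounds, at no more than -0.02) and MAP1LC3A by -0.19. MAP1LC3C was not well above background on either array. The ATG8 list as a whole, with GABARAPL1 and GABARAPL3 in it, had a median of -0.14 over 6 genes (percentile 10.2 among matched random lists).

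**Figure D1:**
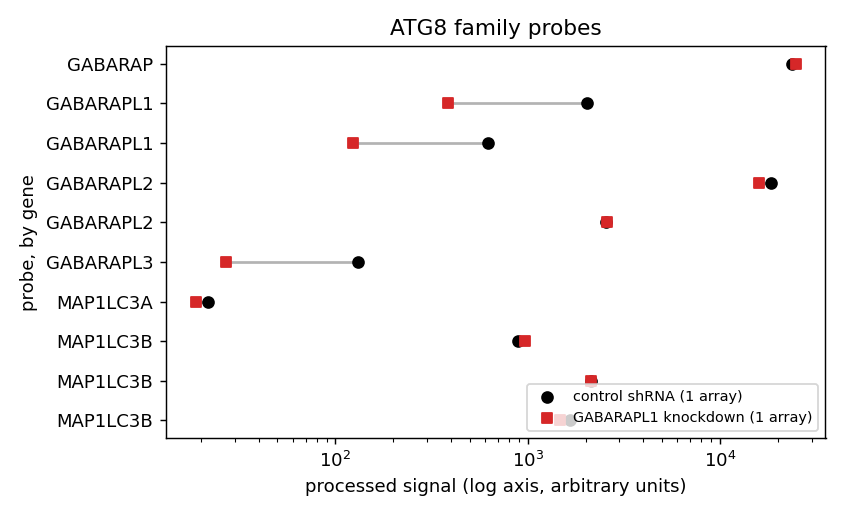
Processed signal (log axis, arbitrary units) of each measured ATG8-family probe on the control array (black circles) and the knockdown array (red squares), 1 array each, with a line joining the pair. Both GABARAPL1 probes and the GABARAPL3 probe were lower on the knockdown array, while the other probes nearly overlapped.

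The next comparison asked which other transcripts differed with the knockdown. Among well-expressed genes, the largest positive differences were those of ID1 (1.57) and ID3 (1.35), inhibitors of helix-loop-helix transcription factors, and of DICER1 (1.33, both probes 1.23 or more), the RNase that processes microRNA precursors. ALB (1.31) and TTR (1.30), plasma proteins typical of liver, followed, with GUSBP4 (1.24), the phosphatase DUSP2 (1.05), ESF1 (1.03), AGR2 (0.96) and the interleukin-6 receptor IL6R (0.96). The largest negative difference was that of CRIP2, at -4.66, from a single probe in the outermost column of the array. GABARAPL1 came next, followed by the dehydrogenase DHRS2 (-1.82), CMPK1 (-1.67), the cell-cycle transcription factor MYBL2 (-1.48), the organic cation transporter SLC22A3 (-1.43), NETO2 (-1.40), DRAP1 (-1.34), ARL2BP (-1.33) and the ER chaperone calreticulin, CALR (-1.32). DHRS2, SLC22A3, NETO2 and DRAP1 each had 2 probes that were all lower by 1.26 or more in size on the log2 scale. CALR had 1 probe, and 1 of the 18 bright spots within 2 positions of it was at -3.63.

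In total, 59 genes were at least 2-fold higher and 133 at least 2-fold lower on the knockdown array, 1.36% of those measured. Lower genes thus made up 69.3% of this set, and 81.6% under cyclic loess. Without the filter on dim probes the split turned, with 617 genes higher and 453 lower (42.3% lower). Of 17004 pairs of replicated spots read in the same way, 6 (0.0353%) were 2-fold apart. Spots flagged as population outliers had been left out first, and both spots of a pair lay on the same array. Of the 206 replicated probes, 133 were at or above the median level. The share is therefore no error rate for the genes past 2-fold. Dim genes contributed most: 8 higher and 30 lower genes lay at or above the median level, against 51 and 103 below it. Of the genes with several measured probes, all 10 that were 2-fold higher and 29 of 31 that were 2-fold lower had every probe on the same side. These genes were chosen by the mean over the same probes, so this agreement was largely built in and is no separate check. Over all genes with several measured probes, the differences of 2 probes correlated with an r of 0.58. This r was 0.67 at or above the median level and 0.53 below it. With normexp background correction, which draws dim signals together, 13 genes were higher and 35 lower. Of all measured genes, 54.7% (Wilson 95% interval 53.9% to 55.5%, counting error only) were higher on the knockdown array, a share that was 47.2% under cyclic loess.

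**Figure D2:**
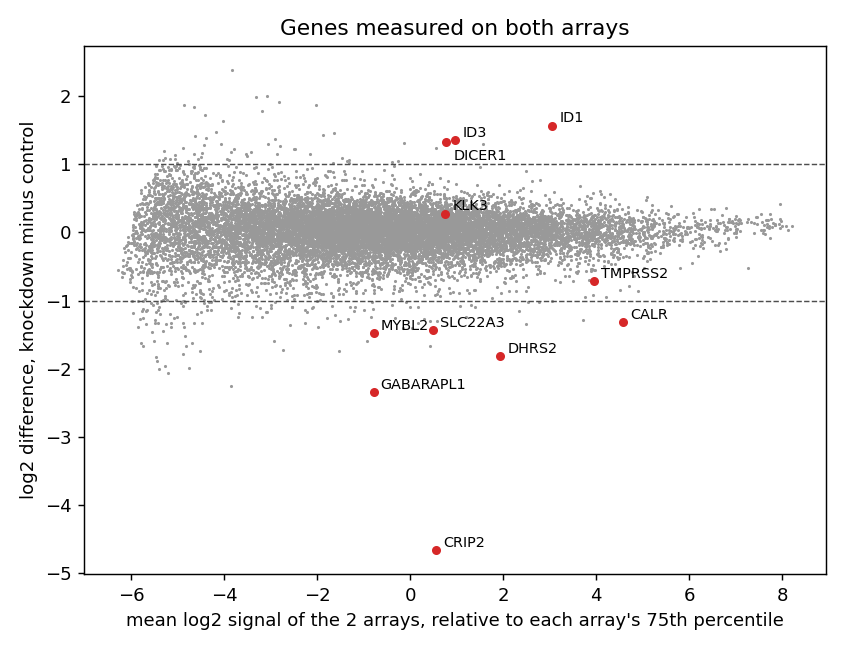
Log2 difference (knockdown minus control, vertical axis) against mean log2 signal relative to each array's 75th percentile (horizontal axis) for the 14088 genes measured on both arrays; dashed lines mark 2-fold and red points are genes named in the text. The scatter widens towards low signal, GABARAPL1 lies at -2.34 and CRIP2, from 1 probe, at -4.66.

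A further 144 genes were well above background on the control array only, 94 of them with a lower bound of 2-fold or more. On the knockdown array only there were 838, 26 of them with such a bound. The knockdown array also had the lower background noise (SD of negative controls 1.67 against 2.27). Its lowest level well above background was lower too (log2 -6.67 against -6.12 after scaling). This allows larger bounds for genes seen on the control array only, so counts and bounds of the 2 directions are not directly comparable. LRRC38 was at least 8.30-fold lower on the knockdown array, the muscle creatine kinase CKM at least 7.11-fold and SERPINB13 at least 6.57-fold; for LRRC38 and SERPINB13 the bound rests on 1 probe, as the other probes, 1 and 2, were not well above background on either array. A spot touching that of LRRC38 was at -4.20, and spots within 2 positions of those of CKM and SERPINB13 were at -3.80 and -1.87. RGS1, a regulator of G-protein signalling, was at least 4.03-fold higher on the knockdown array, FGF18 at least 2.83-fold and CHI3L1 at least 2.82-fold. The 2 probes of FGF18 differed by 2.35 and 1.34 (log2) and those of CHI3L1 by 1.67 and 1.22. For both genes the second value lies below the gene's bound.

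Whether genes that androgen induces differed in level was asked with 34 such genes, all measured. The 2 arrays hold no comparison with and without androgen, so a response to androgen was not measured. Of these, 25 were lower and 9 higher on the knockdown array, with a median of -0.23, below all 10000 matched random lists (percentile 0). The lowest were the metalloreductase STEAP4 (-1.33), the prostaglandin-degrading enzyme HPGD (-0.94), ELL2 (-0.78) and the protease TMPRSS2 (-0.72). STEAP4 was dim, and its difference was -0.43 with normexp background correction and -0.42 with no filter on dim probes. Members were not uniform. FKBP5 differed by -0.22 (2 probes, -0.41 and -0.03), while KLK3, which encodes prostate-specific antigen, was higher by 0.27 (3 probes, -0.04 to 0.48). The 11 androgen-repressed genes had a median of -0.09 (percentile 10.9), with UGT2B11 at 0.69, UGT2B15 at 0.56, CCN3 at 0.52 and MET at -0.57 (0.41 with no filter on dim probes). Without the filter on dim probes the same 11 genes had a median of 0.41 and stood apart as higher (percentile 100), so no direction can be given for them. Luminal identity genes had a median of -0.07 (percentile 5.79), with AGR2 at 0.96, TFF3 at -0.66, SPDEF at -0.49 and KRT19 at 0.40. They stood apart as lower with the brightest probe per gene (median -0.10, percentile 2.33) and over the 9 members with 2 or more probes (median -0.23, percentile 0.285).

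Chaperone and stress genes of the endoplasmic reticulum were lower as a group. Of 21 chaperone and stress genes, 18 were lower, with a median of -0.26, again below all random lists (percentile 0); with the brightest probe per gene the median was -0.16 (percentile 0.24). Beside CALR they included DERL2 (-0.96), which acts in the export of misfolded proteins, and the co-chaperones DNAJB9 (-0.66) and DNAJC3 (-0.65). A second DNAJC3 probe, which did not count as measured, was at 0.48. ATF4 targets, another branch of the response to misfolded proteins, had a median of -0.05 (percentile 5.82), with ALDH1L2 at -0.65, VLDLR at -0.56 and TRIB3 at -0.49. Heat shock genes did not stand apart (0.14, percentile 94.6), with CHORDC1 at 0.54, HSP90AA1 at 0.51, HSPA4L at 0.41 and HSPA8 at -0.53; after subtraction of the local median they did, as higher (0.18, percentile 98.9).

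Hypoxia and glycolysis genes were also lower, 28 of 33, with a median of -0.20 and percentile 0. Carbonic anhydrase CA9 differed by -0.85, ANKRD37 and the glycolytic enzyme ENO2 each by -0.80 and the lysyl oxidase LOX by -0.58. CA9 was dim, and its difference was -0.18 with normexp background correction. NDRG1 stands in both this list and the androgen-induced one. Oxidative phosphorylation genes had a median of 0.02 (percentile 54.2), with COX5B at -0.35 and NDUFB3 at 0.29.

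**Figure D3:**
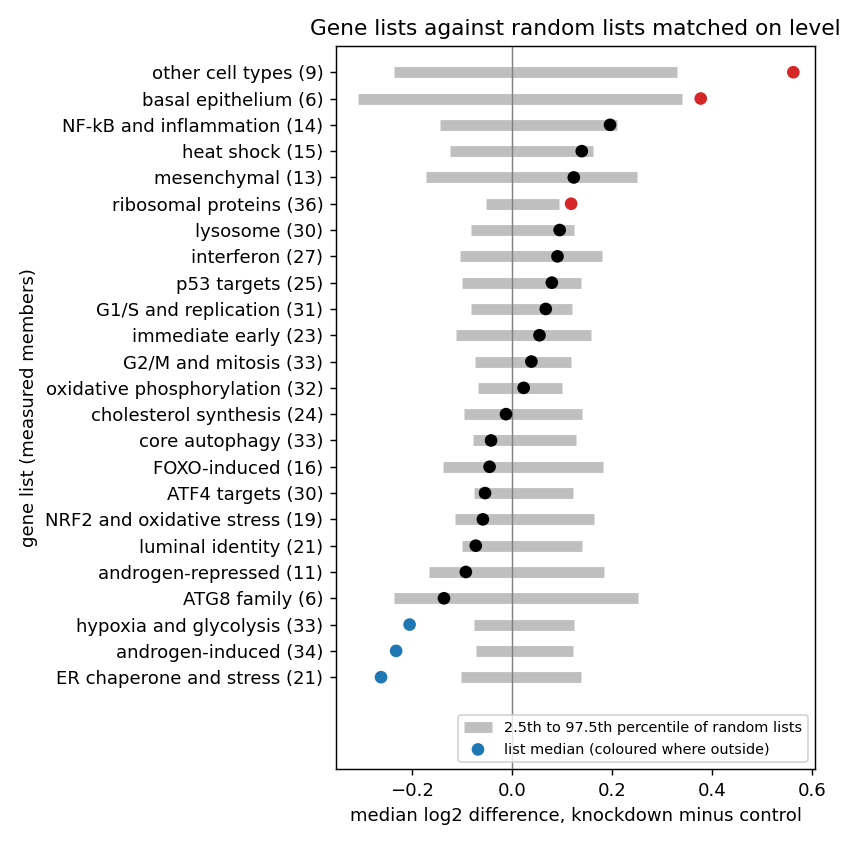
Median log2 difference (knockdown minus control) of each gene list with at least 5 measured members (points, number measured in brackets), with grey bars for the central 95% of 10000 random lists matched on level; blue and red points lie outside. The androgen-induced (-0.23), ER chaperone (-0.26) and hypoxia (-0.20) lists lie below their bars, and ribosomal proteins, basal epithelium and other cell types above.

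Autophagy and lysosome genes did not stand apart. Core autophagy genes had a median of -0.04 (percentile 8.81) over 33 genes, with the receptor OPTN at -0.70, WIPI2 at -0.59, WIPI1 at -0.47 and ATG3 at 0.41 (-0.02 with its brightest probe). Lysosomal genes had a median of 0.10 (percentile 91.5) over 30 genes, with NPC1 at 0.58, CTSA at 0.54, NEU1 at 0.52 and LIPA at -0.53. FOXO-induced genes had a median of -0.04 (percentile 17.4), with TRIM63 at -0.65, CITED2 at 0.59 and PIK3IP1 at 0.54. TRIM63 was dim, at log2 levels of -5.87 (control) and -6.52 (knockdown). The lowest levels well above background on these arrays were -6.12 and -6.67. Cholesterol synthesis genes had a median of -0.01 (percentile 26.2), with MSMO1 at 0.40 and FDPS at -0.35.

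None of the proliferation, stress-response and signalling lists that follow stood apart in the main setting. G1/S and replication genes had a median of 0.07 (percentile 81.3), with CCNE2 at 0.79, POLA1 at 0.36, RFC3 at -0.50 and CDT1 at -0.34; with the brightest probe per gene RFC3 was at 0.18 and the genes stood apart as higher (0.13, percentile 97.9). Those of G2/M and mitosis had a median of 0.04 (percentile 62.6), with AURKA at 0.56 and TTK at 0.41 beside MYBL2 at -1.48. The p53 targets had a median of 0.08 (percentile 82.0), with ZMAT3 at -0.57, GDF15 at -0.52 and FAS at 0.43. Immediate early genes had a median of 0.06 (percentile 66.8), with FOS at -0.89, DUSP6 at -0.80 and JUNB at 0.50. Interferon genes had a median of 0.09 (percentile 73.8), with BST2 at 1.29, MX2 at 0.69 and HERC5 at -0.55. BST2 and MX2 were dim, at mean log2 levels of -4.06 and -4.86 against a median of -0.81 over measured genes. For NF-κB and inflammation genes the list median was 0.20 (percentile 96.3), with TNFAIP3 at 0.61 and SOD2 at -0.41 (0.09 with no filter on dim probes). A second TNFAIP3 probe, which did not count as measured, was at -0.56. The list stood apart as higher with normexp (0.12, percentile 97.6). With 2 further members, seen on 1 array only, entered at their lower bounds, its median was 0.2098. The random range for the 14 measured members ended at 0.2093. For NRF2 and oxidative stress genes the list median was -0.06 (percentile 10.8), with HMOX1 at 0.63 and ABCC2 at -0.58 (0.09 with no filter).

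Among the lists above their random range, ribosomal protein genes were higher in 35 of 36 cases, by a small amount (median 0.12, percentile 99.5), led by RPS23 (0.35), RPS3 (0.30), RPL38 (0.27) and RPL11 (0.25). That list did not stand apart under quantile normalization (median 0.05), with normexp (0.04), with the deposited value table (0.03) or after removal of the trend on probe GC content and level, which left a median of 0.0084 (percentile 73.8). All 6 of the 12 basal epithelial markers that were measured were higher (median 0.38, percentile 98.7), with LAMB3 at 0.80, KRT15 at 0.63, KRT6A at 0.57 and KRT14 at 0.18. This call too was lost under quantile normalization (0.28), with normexp (0.11), with the deposited value table (0.27) and without the filter on dim probes (0.30 over 12). With 2 further markers, seen on 1 array only, entered at their lower bounds, the median was 0.17. That lies inside the random range for the 6 measured markers (-0.31 to 0.34). Markers of other cell types, a mostly dim set, were higher in 8 of the 9 measured of 23 (median 0.56, percentile 100), with COL3A1 at 1.19, CD14 at 1.07, ACTA2 at 0.89 and CD3E at 0.66. The median was 0.22 with normexp and, over all 23 without the filter on dim probes, -0.21. Other COL3A1 probes, which did not count as measured, were at 1.34 and -0.53. Mesenchymal genes had a median of 0.12 (percentile 76.0), with 8 of 13 higher: ANXA1 was at 0.79, SPARC at 0.71, SNAI2 at 0.63 (-0.06 with no filter on dim probes) and TGM2 at -0.41. Only 2 neuroendocrine markers were measured, ENO2 (-0.80) and CHGA (0.34), too few for a percentile.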

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

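Probes with no current gene symbol stood outside the comparisons of genes. Among those at or above the median level, 4 were at least 2-fold higher on the knockdown array than on the control array. A_24_P280897, at chromosome 19, 34080246 to 34080305 (hg19), had a log2 difference of 1.72, with a signal of 1097 on the control array and 3562 on the knockdown array. Probe A_32_P199923, at chromosome 14, 95556197 to 95556256, differed by 1.27 and overlaps the DICER1 probe at 95556233 to 95556292, which differed by 1.43. A_24_P681563 differed by 1.21 and A_24_P675947, at chromosome 4, 153472474 to 153472533, by 1.17. In the same set 5 probes were at least 2-fold lower: A_32_P48066 (-1.30), A_24_P144666 (-1.27, signal 7501 to 3058), A_23_P111766 (-1.22), A_32_P13337 (-1.02) and A_24_P349756 (-1.02, signal 15423 to 7481).

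The tests of the patterns below were chosen after the patterns had been seen, and the test of many cell types after some of its markers' values had been seen too. A few genes typical of liver were higher on the knockdown array: beside ALB (signal 496 to 1212) and TTR (1618 to 3917), GC differed by 2.38 and FGL1 by 1.90, the last 2 chosen after their values were seen. Liver genes as a group were not, and RNA of liver-type cells is argued against: of 30 other liver markers, listed before this test, 12 were measured, with 3 higher and a median difference over all 12 of -0.10 (bootstrap 95% interval -0.35 to 0.08). HP was at 13830 and 13370, and abundant liver transcripts such as APOA1 (3.65 and 4.41) and FGB (2.79 and 1.91) were not well above background on either array, while 6 of the 30 (AMBP, C3, CP, F2, FGG and ITIH3) were so on the knockdown array only, at signals of 10.6 to 20.3 there and 3.14 to 12.8 on the control array. RNA of many cell types, as in a reference mixture, is argued against as the source of these genes by the same liver values, since it would have to bring liver RNA too. That rule was written after values had been seen, so it follows from the liver result and is no separate test. The mixture's own markers alone did not decide. A median under 0.3 was set against the mixture, and was taken as met only where the upper end of the bootstrap interval was under 0.3. The medians that follow were under 0.3, but their intervals reached above it. The 20 pooled from 6 other cell types had a median of 0.19 (interval 0.00 to 0.39). The 16 not also in the list of other cell types, whose values had been seen, had one of 0.15 (-0.16 to 0.38). An effect of the knockdown or a difference between the cultures was not tested and also remains open.

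A group of 7 touching spots was at least 2-fold lower on the knockdown array, in rows 13 to 17 and columns 76 to 78, whereas the largest such group in 100 shuffles of the positions had 4 spots. It held probes for KLHL23 (1488 to 2.63), RAD23B (418 to 2.64), CDC25A (722 to 94.4) and RBPJ. Other probes of these 4 genes elsewhere on the array, 6 in all, had a median difference of 0.00389 (range -0.18 to 0.14), consistent with a local defect of the knockdown array. Without the group, 132 genes in place of 133 were at least 2-fold lower; the gene that dropped out was CDC25A. Single defective spots cannot be found this way, so CRIP2, CALR and other genes with 1 probe keep that doubt.

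The androgen-induced, ER chaperone and hypoxia lists were lower together. GC content and brightness of the probes as the whole source are argued against, since after removal of their trend the highest percentile of the 3 lists was 0. A broad trend over the array as the whole source is argued against in the same way, with a highest percentile of 0 after the local median was subtracted. A median of 11 by 11 spots does not see small defects: at LRRC38 it was -0.06, although a touching spot was at -4.20. Small defects at single members were therefore not covered. What stays open is a difference between the 2 cultures, RNA preparations or slides unrelated to the shRNA, an off-target effect of the shRNA, and an effect of lower GABARAPL1; with 1 array per group these could not be separated, and none was tested.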

How the results depend on the processing

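No paired analysis was possible because each group had 1 array, which leaves no replicates to pair. Scalings and backgrounds moved GABARAPL1 past its technical spread only with normexp (-2.04). At least 2-fold higher and lower genes numbered 13 and 35 with normexp, 617 and 453 with no filter on dim probes, 9 and 41 with probes in the upper part of the level range, 453 and 585 at 1.5-fold, and 10 and 29 among genes with 2 or more probes on one side (chosen after seeing the data). Lower genes were 42.3% of those past 2-fold with no filter, against 69.3%; surrogate values of dim probes enter there. All 13 and 35 genes left by normexp, and the 41 higher genes left by loess, were in the main sets, and loess kept all 133 lower ones among 182. The share of genes higher was 50.5% when centred on the median, 50.6% with quantile normalization, 47.2% with loess, 50.9% with normexp, 50.8% with the deposited table, 52.5% with no filter and 53.7% in the upper part, so it follows the scaling and shows no excess of its own. The androgen-induced, ER and hypoxia calls held in all 13 alternatives (medians -0.26 to -0.21, -0.29 to -0.16 and -0.26 to -0.19). ER medians that moved were -0.19 with normexp, -0.18 with no filter and -0.16 with the brightest probe; that of hypoxia was -0.26 after the GC and level trend was removed. Ribosomal medians were 0.0545 (quantile), 0.0734 (loess), 0.0381 (normexp), 0.0251 (deposited table) and 0.0084 (GC and level trend removed); the call ended in all of these but loess. The basal median was 0.11 with normexp, and that call ended with normexp, quantile, the deposited table and no filter. The other-cell-type median was 0.22 with normexp and reversed to -0.21 with no filter, where 23 members enter in place of 9. Of the 18 lists that did not stand apart, androgen-repressed, luminal, G1/S, NF-κB and heat shock genes did under 1 or 2 alternatives each, with the values given beside them. The cause of the other moves was not tested. Of the 118 named genes none past 2-fold turned direction under the 10 alternatives run gene by gene. Of these alternatives, no filter, upper part, brightest probe, local median and removal of the low spots were added after seeing the data. Below 2-fold, ABCC2, MET, SNAI2 and SOD2 turned with no filter, and ATG3, CCNG2 (-0.37 to 0.36) and RFC3 with the brightest probe and in the upper part; the other turns were of values near 0. The largest move was 1.09, and normexp gave 45 of 90 moves.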

Other observations

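The genes of this paragraph were chosen after their values were seen. Among dim genes, the fatty-acid-binding protein FABP5 was higher on the knockdown array by 1.47 over 4 probes (0.42 to 2.02), the tyrosine kinase BMX by 2.0 over 2 probes (1.87 and 2.13) and IGFBP3, a binding protein of insulin-like growth factors, by 1.45 over 2 (1.54 and 1.36). SOCS3, an inhibitor of cytokine signalling, differed by 1.98 and the double-stranded RNA receptor TLR3 by 1.78, from 1 measured probe each. Among genes with several probes that were all lower, PLCB1 differed by -1.72 (2 probes), ERGIC1 by -1.08 (5), WDR1 by -1.10 (4) and CD55 by -1.10 (3).

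The test of this paragraph was chosen after ID1 and ID3 had been seen. Both are direct targets of BMP/SMAD signalling, so higher BMP/SMAD signalling on the knockdown array was put forward as a hypothesis, with 12 other targets listed before their values were examined. Of these, 10 were higher, with a median of 0.28 (bootstrap 95% interval 0.15 to 0.52; 99.5th percentile of matched random lists). HEY1 differed by 1.15, ID4 by 0.84, BAMBI by 0.57, SMAD7 by 0.48, ID2 by 0.42 and KLF10 by -0.23. HEY1 was dim, with a signal of 79.5 on the control array and 174 on the knockdown array. The alternatives were not applied to this list of targets. The median lay between the 0.5 set in advance for the hypothesis and the 0.2 set against it, so BMP/SMAD signalling remains a candidate explanation that these 2 arrays leave undecided.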
